A study of Homo sapiens with 2 samples.

How the data were processed

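Binding of the retinoblastoma protein Rb was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the prostate cancer cell lines VCaP and LNCaP, with 1 library per line. Per the labels' protocols, cells at passage 10 to 15 were kept for 3 days in medium with 5% charcoal-stripped serum, which is low in steroid hormones, and then received 10 nM of the androgen dihydrotestosterone (DHT) for 4 h. Chromatin was crosslinked with formaldehyde, sonicated and precipitated with a mouse monoclonal antibody against Rb, per the labels' protocols. Cells without DHT, input chromatin and replicate cultures were not analysed here. Each library was assigned to its cell line from the cell line label.

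Per the file headers, the authors called peaks in each library on its own with MACS version 2.1.0.20140616, without a control library, at a q-value limit of 0.05. The same headers give 75 bp tags, 1 tag kept per position, an effective genome size of 2790000000 bp, a band width of 250 bp and model limits of 10 and 30. They also give a modelled fragment length of 225 bp in VCaP and 241 bp in LNCaP. The submitters' processing notes name the genome build hg19 and the tools MACS2 and HOMER. What HOMER was used for, and the aligner, are not given in the sources used here. Because no control was used, each peak was called against the tags of its own library, with the higher of the genome mean and the density in a window of 10000 bp around the peak as background.

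The deposited pileup is a coverage signal: the number of extended tags that cover the peak's summit, not scaled to library size. The deposited fold enrichment is a ratio that the authors' peak caller formed from the pileup and the local background. The deposited significance values are −log10 p and −log10 q from the same caller. The deposited peak length is in bp, per the file headers. These scores belong to each peak in its own library. They were used here to describe, rank and filter peaks within a list, and where fold enrichment is set side by side for overlapping peaks it remains each library's ratio to its own background. The summit files repeated the summit positions and scores of the peak tables in all 9423 VCaP and 21994 LNCaP rows, and the numbering of peaks had no gaps.

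The fold enrichment equalled the pileup plus 1 over the background plus 1, so that the background of each peak could be computed back. Expressed as tags in the 10 kb window, it came out whole within 0.05 tags for 100% of the peaks whose background lay above the genome mean. The smallest background recovered was 0.701 tags per fragment length in VCaP and 0.317 in LNCaP, the genome mean given by the tag number, fragment length and genome size. This genome mean was the background of 1.73% of VCaP and 5.97% of LNCaP peaks. Over 10 kb it equals 31.2 tags in VCaP and 13.2 in LNCaP, and the windows of these peaks hold at most about that many. The tags of the peak itself are part of its window.

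Overlap was counted between peaks on chromosomes 1 to 22 and X that shared at least 1 bp. Where several peaks overlapped, the partner with the highest fold enrichment was taken. Shares are given with exact 95% binomial intervals (Clopper-Pearson), which cover counting error only. The chance level of the overlap came from 1000 circular shifts of the LNCaP peaks within each chromosome. Spearman's rho of fold enrichment was computed across overlapping pairs, with an interval from 1000 bootstrap draws; peaks are not replicates, and no p-value is attached. The median fold enrichment of shared peaks was ranked among 10000 random draws of as many peaks from the same list. The share of peaks on each chromosome was set side by side with exact intervals. No test between the cell lines was possible, since each is represented by 1 library.

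The comparisons and tests named so far, most of the alternative settings and the rule for named peaks were fixed before the data were examined. Named were the 10 peaks of highest fold enrichment in each library, the 10 shared peaks with the best worse rank over both libraries, and the 5 highest peaks of each library without overlap in the other. Mitochondrial and unplaced sequence was left out of the ranking. The alternatives fixed then were stricter limits on −log10 q (at least 5) and fold enrichment (at least 5 or 10), reciprocal overlap of at least 50%, summits within 200 bp, gaps of up to 1 kb, lists of equal length, and pileup in place of fold enrichment.

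The following choices were made after seeing the data. A second chance level displaced the LNCaP list as a whole by 10 to 100 kb, which keeps the regional density of peaks. Peaks whose window held more than 5 times the list's median tag number were left out in an alternative. Windows were compared between the lines as the log2 ratio of VCaP over LNCaP tags, each scaled to 1000000 tags of its library, at overlapping pairs. Relations along the genome were computed over 10 Mb bins with at least 10 pairs, and their p-values come from rotating one series of bins against the other. The tags of the peak itself were taken off each window in alternatives, either as the tags over the summit or as the pileup times the length over the fragment length, with the rest summed per bin. The larger estimate came to a median of 75.3% of the window in LNCaP pairs and 31.2% in VCaP pairs. The regions of chromosomes 8, 13, 16 and X, the bins of 1 Mb and the intervals of at least 2.5 Mb without a peak in either list, chromosome starts included, were also chosen then.

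The 22 gene lists and 17 motifs fixed beforehand were not used, because a genome and annotation of hg19 were not used here and the gene table at hand is for GRCh38.p14. For the same reason the share of peaks at transcription start sites was not computed and peaks are named by position only, with no statement on genes, exons or introns. All positions are hg19 as in the deposited peak tables. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap counts were checked against bedtools 2.31.1. Tested on simulated data for the comparison of VCaP with LNCaP, the overlap step recovered 2000 of 2000 planted overlaps among 5000 simulated peaks.

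Depth differed between the libraries. After removal of duplicates, VCaP had 8691938 of 8693799 tags and LNCaP 3671482 of 3672991, per the file headers. At this depth, the weakest deposited peaks rested on a pileup of 6 tags in VCaP and 4 in LNCaP.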

Results

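Sites bound by Rb, the retinoblastoma tumour suppressor protein, which restrains the cell cycle largely through E2F transcription factors, were mapped in a pair of prostate cancer cell lines, VCaP and LNCaP. Both lines express the androgen receptor, and both had been exposed to 10 nM DHT for 4 h after 3 days in hormone-depleted serum. The series was designed to examine where Rb lies on the genome of these lines under that treatment. The measurement in each line is the authors' list of peaks, regions with more immunoprecipitated tags than the surroundings of the same library. There are no replicates: each line has 1 library, so that differences between the lists compare these libraries and carry no test between the lines.

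LNCaP gave the longer list of Rb peaks, from the shallower library. The LNCaP list held 21994 peaks and the VCaP list 9423, a ratio of 2.33. LNCaP peaks were also broader, with a median length of 395 bp (quartiles 267 and 589) against 313 bp (250 and 418) in VCaP. They covered 10085 kb of the genome in LNCaP and 3336 kb in VCaP. The library of LNCaP had 3671482 tags after filtering, 0.422 times the 8691938 tags of VCaP, so that peaks per 1000000 tags came to 5990 in LNCaP and 1084 in VCaP.

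Peaks had a similar median fold enrichment in both lists, and the ratio of LNCaP to VCaP peaks was higher among strongly enriched peaks. The median fold enrichment over the local background, as the authors' peak caller gave it, was 6.00 in LNCaP (quartiles 4.99 and 7.59) and 5.51 in VCaP (4.83 and 6.45). The median summit pileup was 13 tags in both, which is 3.54 per 1000000 tags of the library in LNCaP and 1.496 in VCaP. At a fold enrichment of at least 10, LNCaP had 1762 peaks and VCaP 314, a ratio of 5.61. With −log10 q of at least 5 the counts were 14562 and 5204, a ratio of 2.80. The highest fold enrichment was 23.5 in VCaP and 22.8 in LNCaP.

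In the full lists, most Rb peaks of VCaP overlapped an Rb peak of LNCaP, while most LNCaP peaks had no counterpart in VCaP. On chromosomes 1 to 22 and X, 6688 of 9393 VCaP peaks were overlapped by an LNCaP peak, or 71.2% (95% interval 70.3 to 72.1). From the LNCaP side, 6634 of 21955 peaks were overlapped, or 30.2% (29.6 to 30.8). This left 2705 peaks in the VCaP list and 15321 in the LNCaP list without a counterpart. When LNCaP peaks were shifted around each chromosome, on average 0.704% of VCaP peaks and 0.303% of LNCaP peaks were overlapped, and the highest of 1000 shifts gave 1.00% and 0.437%. A displacement by only 10 to 100 kb, chosen after seeing the data, gave 1.302% and 0.560%. Both statements depend on the setting: with the 9393 peaks of highest fold enrichment from each, 52.0% of VCaP and 51.0% of LNCaP peaks were overlapped. When each peak had to cover at least 50% of the other, the shares were 42.8% and 18.3%.

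Sites shared by both lines were the more enriched and broader sites in each. In LNCaP, shared peaks had a median fold enrichment of 7.68 (quartiles 6.16 and 9.53) against 5.51 (4.74 and 6.64) for unshared peaks, and a median length of 580 bp against 325 bp. In VCaP the medians were 5.71 (4.96 and 6.74) and 5.14 (4.56 and 5.81), with lengths of 344 and 265 bp. In each list the median of shared peaks lay above all 10000 random draws of as many peaks, of which the highest reached 6.07 in LNCaP and 5.53 in VCaP. In the decile of LNCaP peaks with the lowest fold enrichment, 10.3% were shared (9.10 to 11.7), and in the highest decile 75.3% (73.4 to 77.1). The corresponding VCaP shares were 51.4% (48.2 to 54.7) and 89.3% (87.1 to 91.2).

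**Figure D1:**
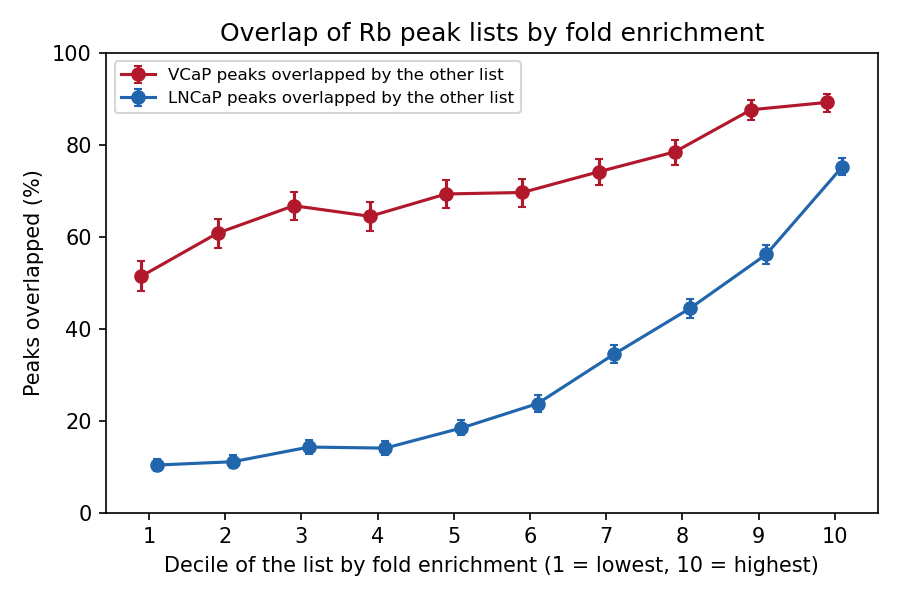
Share of Rb peaks overlapped by a peak of the other cell line (%, vertical axis) in each decile of the list ordered by fold enrichment (horizontal axis, lowest to highest), for VCaP (red) and LNCaP (blue); bars are exact 95% binomial intervals. The share went from 51.4% to 89.3% in VCaP and from 10.3% to 75.3% in LNCaP between the lowest and the highest decile.

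At shared sites the summits lay close together, and the order of the peaks by enrichment was only partly alike. The summits of the 6688 overlapping pairs were a median of 73 bp apart (quartiles 30 and 155), and 82.6% lay within 200 bp. Spearman's rho of fold enrichment across these pairs was 0.35 (bootstrap interval 0.33 to 0.37), and that of pileup was 0.46 (0.44 to 0.48). Peaks are not independent replicates, so these are descriptions of the pairs. Fold enrichment was the higher in LNCaP in 5403 pairs, 80.8% (79.8 to 81.7), with a median ratio of 1.32 (quartiles 1.07 and 1.62). Each fold is relative to the background of its own library, without a control.

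Most of the Rb peaks of highest fold enrichment had a counterpart somewhere in the other list. Of the 10 peaks of highest fold enrichment, 9 in VCaP and 10 in LNCaP were overlapped by a peak of the other line, and of the highest 100, 88 and 95 were. Fewer ranked high in both: 38 VCaP peaks were in both lists' top 100, and 217 in both lists' top 500. A site on chromosome 12 at 57145811–57146298 (VCaP interval) had a fold enrichment of 20.6 in VCaP and 22.5 in LNCaP. It was among the top 10 of both lists together with a site on chromosome 2 at 174219267–174219694, with 20.6 in VCaP and 22.01 in LNCaP, and a site on chromosome 9 at 44070541–44070936, with 19.9 and 21.9. Next among shared sites came chromosome 21 at 11186441–11186991, with 18.3 in VCaP and 21.7 in LNCaP, chromosome 1 at 155214496–155214904, with 18.5 and 20.4, and chromosome 11 at 9594891–9595362, with 18.0 and 20.8. The remaining 4 of the 10 best shared sites were on chromosome 12 at 124086239–124086725 (17.3 in VCaP and 19.99 in LNCaP), chromosome 22 at 18717954–18718268 (23.5 and 19.2), chromosome 17 at 57642614–57643054 (16.4 and 19.001) and chromosome X at 108297373–108297832 (16.9 and 18.9). The site on chromosome 22 was the highest of the VCaP list. Both lists were called without a control, so that overlap alone does not show Rb binding at these sites.

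Several leading sites had unequal enrichment in the lines. The highest LNCaP peak, on chromosome 12 at 10765913–10766371, had a fold enrichment of 22.8 in LNCaP and 10.2 in VCaP. LNCaP peaks on chromosome 4 at 122722310–122722773, chromosome 11 at 74303445–74303979, chromosome 14 at 55493563–55494146 and chromosome 1 at 63988789–63989238 had folds of 21.7, 21.1, 21.01 and 20.8, and their VCaP partners had 12.6, 12.3, 12.3 and 12.6. On chromosome 9 at 17134716–17135219 the values were 22.2 in LNCaP and 15.7 in VCaP. The opposite order was seen for a VCaP peak on chromosome 9 at 67320526–67320984, with 20.8 in VCaP and 7.38 in LNCaP. Smaller differences in that direction were found on chromosome 2 at 136633814–136634298 (20.1 in VCaP and 18.5 in LNCaP), chromosome 20 at 35724169–35724702 (19.2 and 17.8) and chromosome 12 at 123011537–123012028 (18.3 and 15.2). Each of these sites was named as 1 of the 10 highest of 1 list, a choice that by itself favours a lower fold in the other line. The VCaP partners of these LNCaP peaks ranked between 34 and 283 of 9393 VCaP peaks. Of 21955 LNCaP peaks, the partner at 67320526–67320984 on chromosome 9 ranked 6028, and the other LNCaP partners ranked between 36 and 151. With 1 library per line, the spread of these values between cultures is not known.

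The 5 highest peaks found in the VCaP list alone lay near long stretches without peaks, and the 5 highest found in the LNCaP list alone did not. The 5 highest unshared VCaP peaks were on chromosome X at 61720757–61721166 (fold enrichment 20.2), chromosome 2 at 92281268–92281556 (18.1), chromosome 9 at 66971267–66971557 (17.5), chromosome 4 at 49659443–49659824 (17.1) and chromosome 11 at 51569918–51570203 (15.8). All 5 lay within 1 Mb of an interval of at least 2.5 Mb that held no peak of either list, as did 28 of the 100 highest unshared VCaP peaks (28.0%, 19.5 to 37.9) and 3.76% of all VCaP peaks (3.38 to 4.16). The 5 highest unshared LNCaP peaks were on chromosome 14 at 83108722–83109105 (18.99), chromosome 8 at 12458771–12459197 (18.4), chromosome 16 at 32199299–32199755 (17.1), chromosome 13 at 46785774–46786261 (16.8) and chromosome 6 at 10404357–10405235 (16.4). None of these lay within 1 Mb of such an interval, against 6 of the 100 highest unshared LNCaP peaks (2.23 to 12.6%) and 3.10% of all LNCaP peaks. Whether shared or not, 16 of the 100 highest VCaP peaks (9.43 to 24.7%) and 2 of the 100 highest LNCaP peaks (0.243 to 7.04%) lay there, among them the shared sites on chromosome 21 at 11186441–11186991 and chromosome 9 at 67320526–67320984. There were 62 such intervals, a measure chosen after seeing the data. The unshared VCaP peak on chromosome 4 itself bounds such an interval. Without a control library, Rb binding at the peaks near these intervals cannot be told apart from background signal.

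Rb peaks were spread differently over the chromosomes in the lines. Chromosome 16 carried 3.77% of LNCaP peaks (828 peaks, 3.52 to 4.03) and 1.96% of VCaP peaks (184 peaks, 1.69 to 2.26), a ratio of shares of 1.93. Chromosome X carried 2.104% of LNCaP and 1.33% of VCaP peaks, and the LNCaP share was also the higher on chromosomes 1, 10, 14 and 18. VCaP had the higher share on chromosome 21, with 188 peaks or 2.001% against 280 peaks or 1.28% in LNCaP, on chromosome 19, with 6.71% against 5.28%, and on chromosomes 9, 11, 13 and 20. On these 12 chromosomes the exact intervals did not overlap, and on the other 11 they did. The total distance between the distributions was 8.61% of peaks (7.55 to 9.88), against at most 3.41% in 1000 pairs of lists drawn from the pooled distribution, which covers counting error only. Both lines are aneuploid, so that DNA copy number can move these shares.

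**Figure D2:**
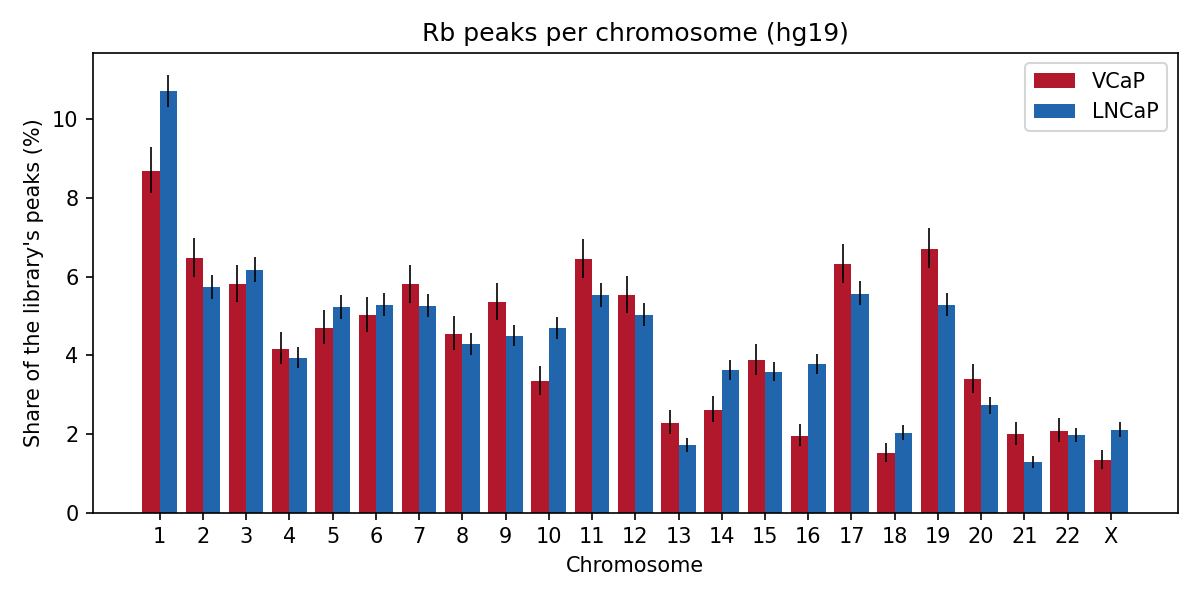
Share of each library's Rb peaks (%, vertical axis) on chromosomes 1 to 22 and X (horizontal axis) in VCaP (red) and LNCaP (blue), with exact 95% binomial intervals. The shares were 8.70% in VCaP and 10.7% in LNCaP on chromosome 1, 1.96% and 3.77% on chromosome 16, and 6.71% and 5.28% on chromosome 19.

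Within chromosome 8, LNCaP peaks outnumbered VCaP peaks by far at the start of the chromosome and by much less over the rest. From 0 to 30 Mb there were 266 peaks in LNCaP and 28 in VCaP, a ratio of 9.50, and from 30 to 140 Mb there were 581 and 346, a ratio of 1.68. The tags in the 10 kb windows around overlapping pairs, scaled to each library's tag number, also differed between these stretches. Their median log2 ratio of VCaP over LNCaP was -2.14 (bootstrap interval -2.26 to -1.97, 26 pairs) from 0 to 30 Mb and -0.49 (-0.58 to -0.35, 184 pairs) from 30 to 140 Mb. The fold enrichment of the same pairs differed little between these stretches, with median log2 ratios of -0.51 and -0.60. In the last 10 Mb, from 140 to 150 Mb, the tag ratio was -2.15 (40 pairs), with 53 VCaP and 93 LNCaP peaks. The median log2 ratio of fold enrichment there was -0.13 (bootstrap interval -0.24 to 0.20). Over all pairs the median tag ratio was -1.24 (quartiles -1.69 and -0.74), and on chromosome 16 it was -2.26. The windows include the tags of the peaks themselves. With summed tags the ratios were -2.12 from 0 to 30 Mb and -0.53 from 30 to 140 Mb, and -1.98 and -0.24 without the tags over the summit. With a larger estimate of the peaks' own tags taken off, which overshot in some bins, they turned to 1.39 and 1.998. From 140 to 150 Mb the summed ratio was -2.06 with all tags and -1.62 with that estimate taken off. On chromosome 16 up to 90 Mb these values were -2.08 and -1.09. These regions were chosen after seeing the data.

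**Figure D3:**
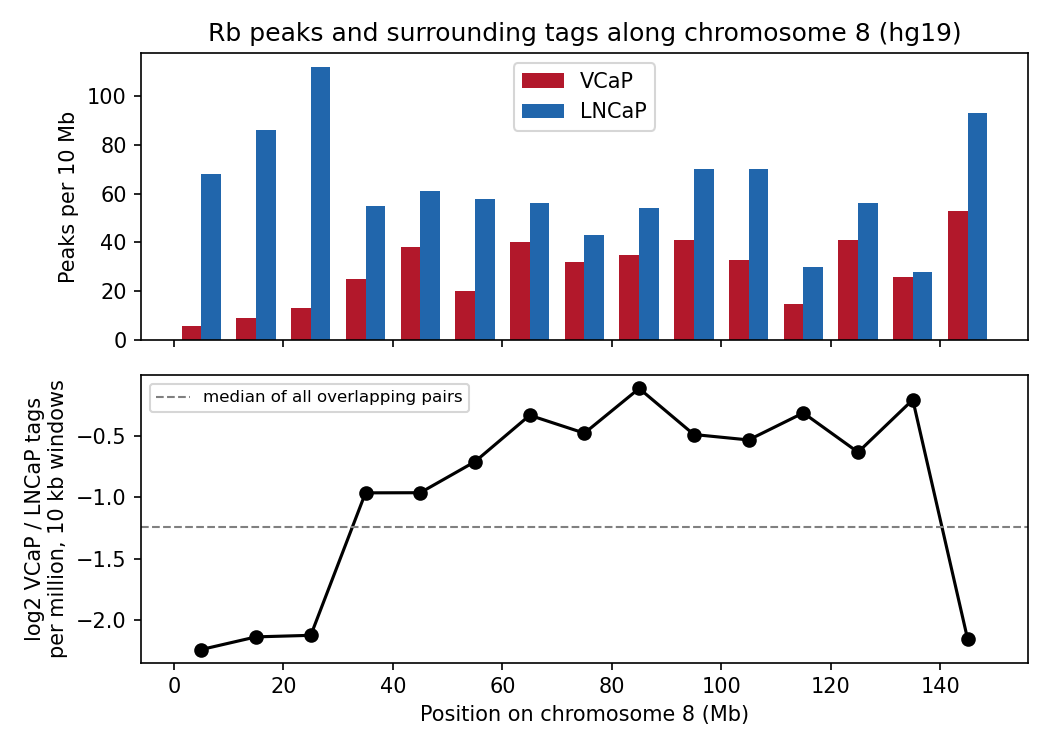
Rb peaks per 10 Mb on chromosome 8 (hg19) in VCaP (red) and LNCaP (blue) in the upper panel, and the median log2 ratio of VCaP over LNCaP tags, scaled to library size, in the 10 kb windows of overlapping pairs in the lower panel, both against position in Mb. The dashed line is the median of all pairs, -1.24; the ratio lay near -2.14 from 0 to 30 Mb and at a median of -0.49 from 30 to 140 Mb.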

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

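The tests of depth, of peaks with a high pileup, of overlapping pairs, of local tags over 10 Mb bins and of fold enrichment in windows with few tags were chosen only after the results they bear on had been seen; those of peak density and of pileup were set down before.

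Mitochondrial sequence was outside the comparisons of the lines and held the highest pileups of both libraries. The VCaP list had 3 mitochondrial peaks with up to 311 tags at the summit and a fold enrichment of at most 2.17, and the LNCaP list 4 with up to 257 tags and at most 6.53.

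The LNCaP list was 2.33 times as long as the VCaP list. Depth argues the other way, since LNCaP had 0.422 times the tags of VCaP. Among peaks with at least 20 tags at the summit, LNCaP had 5347 and VCaP 1605, a ratio of 3.33 (3.15 to 3.52). Marginal calls over a low background therefore do not account for the longer list alone. How much they add below that pileup was not tested. The 5488 LNCaP peaks in the lowest quartile of local tags had a median pileup of 7 tags. A higher enrichment of the LNCaP precipitate throughout is a candidate explanation: the fold was the higher in LNCaP in 80.8% of overlapping pairs. Of the 500 VCaP peaks of highest fold, a choice that works against LNCaP, 281 had a higher fold in LNCaP, or 56.2% (51.7 to 60.6), with the 46 that lacked an LNCaP partner counted as not higher. Whether that lies in the precipitation or in how much Rb the lines have on chromatin stays open, with 1 library per line and no control.

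The ratio of VCaP to LNCaP peak numbers varied along the genome, with for example 28 against 266 at the start of chromosome 8 and 67 against 20 on chromosome 13 from 109 to 113 Mb. Over the 227 bins of 10 Mb with at least 10 overlapping pairs, which leave out most of the start of chromosome 8, the ratio of local tags and the ratio of peak numbers went together with the density of peaks removed (rho 0.56, two-sided rotation p = 0.0044, the smallest that rotations can give), and over the 305 bins with at least 1 pair rho was 0.50. The tags of the peaks themselves are part of the windows: without those over the summit rho was 0.47 (rotation p = 0.0044), and with a larger estimate taken off, which overshot and left no tags in 35 bins, it was 0.09 (rotation p = 0.31) over the other 192. DNA copy number may move where peaks are called in these aneuploid lines, but over the genome it cannot be told apart from the peaks' own tags, because the number of those tags is not known. The relation to the density of peaks was not past chance, with rho 0.11 (rotation p = 0.15), and true differences in Rb binding between the lines stay open as untested.

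LNCaP peaks in windows with few tags were rarely shared: 4.14% (3.62 to 4.70) in the lowest quartile of local tags, with a median of 18 tags per 10 kb, against 51.4% (50.1 to 52.8) in the highest, with 103. The windows include the tags of the peaks themselves, and peaks in the lowest quartile were also smaller. Their median pileup was 7 tags and their median length 248.5 bp, against 22 tags and 548 bp in the highest. Low fold enrichment does not account for the rare sharing alone, since in the top quintile by fold 22.5% (16.9 to 28.9, 200 peaks) were shared in the lowest quartile and 84.0% (82.0 to 85.8) in the highest. At a pileup of 10 to 15 tags the shares were 19.9% (16.1 to 24.1) and 18.7% (16.3 to 21.3). Similar shares had been set down beforehand as the outcome if low pileup were the cause. However, the median fold enrichment was then 7.94 in the lowest quartile and 4.30 in the highest. Low pileup as the cause therefore cannot be told apart from the other differences, since pileup and local tags together set the fold. The corresponding VCaP shares were 54.2% in the lowest and 79.9% in the highest quartile, and a difference in Rb binding between the lines at these sites was not tested.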

How the results depend on the processing

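Leaving out peaks in windows with many tags, restricting counts to chromosomes 1 to 22 and X, equal lists for the chromosome distribution, and the settings for the relation of local tags to peak numbers were chosen after seeing the data; the other settings were planned. LNCaP had the longer list at each setting. Counts were 5204 in VCaP and 14562 in LNCaP at −log10 q of at least 5, and 314 and 1762 at a fold enrichment of at least 10. The shares of VCaP and LNCaP peaks with overlap were 42.8% and 18.3% with 50% reciprocal overlap, 59.0% and 25.2% with summits within 200 bp, and 74.3% and 33.8% with gaps of up to 1 kb. They were 52.0% and 51.0% with lists of equal length, which leave out the LNCaP peaks of lower fold enrichment, and 75.9% and 27.0% at −log10 q of at least 5. At a fold enrichment of at least 5 the LNCaP share was 28.2%, and the VCaP share stayed within its interval. The Spearman correlation across overlapping pairs was 0.46 with pileup and 0.39 with summits within 200 bp. With such summits the median fold of shared peaks exceeded that of unshared peaks by 0.68 in VCaP and 2.32 in LNCaP, against 0.57 and 2.17 with any overlap. Where no construction is named, the cause was not tested. The VCaP share thus fell below 50% with reciprocal overlap, and the LNCaP share rose above 50% with equal lists. Among the results of the comparisons, 19 values moved past their limits and 12 stayed within them. Those that stayed included the VCaP share at a fold enrichment of at least 5. They also included the overlap without the 95 VCaP and 41 LNCaP peaks in windows with many tags. Of 10 values for single chromosomes, 2 moved and 8 did not. The relation of local tags to peak numbers lost its call at 1 of 8 settings, the only one with the larger estimate of the peaks' own tags taken off. The other 7 kept all tags of the window or took off only those over the summit. Not run were the settings planned for start sites, gene lists and motifs. No paired analysis was possible because each line has 1 library. The weakest LNCaP peaks rest on a pileup of 4 tags, and a site without a peak in either list is not shown to lack Rb.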

Other observations

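All of the regions described here were chosen after seeing the data, and the values are given without a test.

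A few stretches held more Rb peaks in VCaP than in LNCaP, against the general ratio. On chromosome 13 from 109 to 113 Mb there were 67 VCaP peaks and 20 LNCaP peaks. The median window there held 208 tags in VCaP and 50.5 in LNCaP before scaling to library size, and 23.9 and 13.8 after scaling. At the 14 overlapping pairs the log2 ratio of scaled VCaP over LNCaP tags was 1.00 (bootstrap interval 0.76 to 1.33), against -1.24 over all pairs. All of these values include the tags of the peaks themselves. The median fold enrichment in this stretch was 4.07 in VCaP and 5.40 in LNCaP. On chromosome X from 66 to 67 Mb there were 6 VCaP peaks and 1 LNCaP peak. Before scaling, the VCaP windows held a median of 453.5 tags and the LNCaP window 49 tags. Scaled to library size, these values were 52.2 in VCaP and 13.3 in LNCaP. The median fold enrichment there was 3.58 in VCaP, and the LNCaP peak had 6.88. In both stretches the VCaP median lay within the range of the lowest decile of VCaP peaks, which reached 4.35. The median window of the whole VCaP list held 68 tags. On chromosome X the VCaP median was above 340 tags, the limit used for leaving out windows with many tags. In total 8 bins of 1 Mb had at least 5 VCaP peaks and at least 3 times as many as LNCaP, 3 of them on chromosome 13, 2 on chromosome 2 and 1 each on chromosomes 8, 19 and X. Those on chromosome 2 from 92 to 93 Mb, chromosome 8 from 46 to 47 Mb and chromosome 19 from 27 to 28 Mb border an interval of at least 2.5 Mb without peaks. Near such intervals, Rb binding cannot be told apart from background signal without a control.

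The densest stretch of Rb peaks in VCaP was on chromosome 11 from 65 to 66 Mb, with 46 peaks, and LNCaP had 45 there. Of the VCaP peaks in that bin, 32 were overlapped by an LNCaP peak. The densest bin of LNCaP, on chromosome 16 from 30 to 31 Mb, also held 46 peaks in LNCaP, and 10 in VCaP, all 10 of them overlapped. On chromosome 17 from 7 to 8 Mb LNCaP had 45 peaks and VCaP 13.

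Peaks within 1 Mb of a long stretch without peaks were more frequent among unshared VCaP peaks, at 6.43% (5.54 to 7.42), than among shared ones, at 2.68% (2.30 to 3.09). In LNCaP the shares were 3.27% (2.99 to 3.56) and 2.71% (2.34 to 3.13).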
